A study of Aegilops tauschii x Triticum turgidum with 4 samples.

How the data were processed

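Gene expression was measured in crown tissue, the base of the shoot that carries the shoot apical meristem, of 3-week-old triploid hybrids between tetraploid wheat and Aegilops tauschii grown at 23 °C. The comparison was between hybrids of wild-type appearance and hybrids with severe growth abortion (SGA), with 2 arrays of each phenotype. The labels name the sampled material in different ways (shoot meristem in the titles, crown in the extraction protocol, leaf in the remarks), and the extraction protocol was followed here. Groups and replicate numbers were taken from the sample titles. The series design speaks of independent experiments but does not say whether they used separate plants, so every p-value measures the spread between these 4 arrays, which may be technical.

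Per the labels' protocols, 0.5 µg of total RNA was amplified and labelled with Cy3, so each array has 1 colour. Per the file headers, spots were quantified with Agilent Feature Extraction (version 9.5 in the submitters' processing notes). The scanner files deposited by the authors hold the linear intensity of each spot; the processed intensity is background-subtracted and spatially detrended within its array, with a small surrogate value for dim spots, and is not normalized between arrays. Each array has 39243 spots, of which 37826 are non-control probes with 37826 distinct names, and no spot was saturated. The authors' deposited value table holds the same intensity times 1 constant per array (1.04 and 1.17 for the wild-type arrays, 0.803 and 0.767 for the SGA arrays). From the values, that constant brings the mean of each array, without the lowest and highest 2% of probes, to about 2500. No source used here states this step. The table is linear, is not centred per probe, and has medians of 248, 266, 403 and 417.

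Probes were taken as log2 of the processed intensity minus the 75th percentile of its array. Control spots were left out, as were 9 probes with an outlier spot. A probe was tested where both arrays of at least 1 group were well above background, which left 30005 probes, of which 27069 were well above background on all 4 arrays. SGA was compared with wild type by limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Figures were drawn with matplotlib 3.10.9. With 2 arrays per group an exact permutation test of 1 value cannot give a two-sided p below 0.333, so values per array are given without a test. For arrays, the number of arrays limits the precision.

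Each slide carried 1 array of each group with the same replicate number, per the file headers, so the replicate number marks the slide and the scan, and pairs the arrays. Deviations from the group means correlated between same-numbered arrays (r = 0.20 across the tested probes, 0.35 across probes measured on all 4 arrays; probes are not independent replicates). The fit with the replicate number as a block is also the fit with the slide as a block. On both slides the wild-type array lay at position 3 and the SGA array at position 4, so position and phenotype cannot be told apart. The sample titles do not name the parents of the hybrids, so a genotype difference between the groups cannot be told apart from phenotype.

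The test was checked on simulated data for the tested probes, with independent noise and no slide effect. The background and outlier filters were not simulated. With 200 of 30005 probes changed, 0%, 35.8% and 65.2% of probes with log2 changes of 0.5, 1 and 2 were recovered, 3 unchanged probes were called, and with no change at all 0 were called. When every probe was changed by its fitted difference, the adjustment was less strict: 91.1% of log2 changes from 0.5 to 1 and 95.7% of those from 1 to 2 were called, with 43 calls of the wrong sign among 22972.

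Before the data were examined, 21 gene lists were fixed as text patterns, together with the rule for the genes named. The files name probes by contig, clone or accession, apart from 6 named by a gene symbol, and no annotation was used here. The lists therefore matched 4 of 37826 names, all in 1 list, and no set test of gene lists was run. For this case the rule allowed at most 2 probe names that rose and 2 that fell, those with the largest fold difference; since values at the background have no order, the ranking was made among probes well above background on all 4 arrays with no overlap of the groups. After the data were seen, probes were also grouped into 35 name classes (the name up to its first digit, with at least 100 tested probes) and tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and medians of single classes were set against 10000 random lists matched on mean signal. A probe above background on both arrays of 1 group and on neither of the other was given a lower bound of its fold: the mean of the bright group against, per dim array, the higher of the lowest signal above background and the probe's own signal.

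The alternatives were median scaling, quantile normalization, normexp background correction (offset 50, on median spot intensities, since the files hold no mean ones), the authors' value table, other filters, the block, each array left out, other variance models and other thresholds. Scaling to the 7 E1A spike-in probes that were well above background on all arrays (synthetic RNAs of known amount, 32 spots each), and to total signal, was added after the data were seen. Where leaving out an array left 1 array in a group, limma pooled the spread, so the lone array was assumed to vary like the other group.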

Results

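Crown RNA of triploid wheat hybrids with severe growth abortion (SGA) was compared with that of hybrids of wild-type appearance on 4 single-colour oligonucleotide arrays, 2 per group, to ask which transcripts differ where shoot growth stops. Each array carried 37826 plant probes. On the wild-type arrays 27627 and 28749 probes were well above background, and on the SGA arrays 29981 and 30258. The arrays within a group were close to each other: Pearson's r across the tested probes, which are not independent replicates, was 0.996 between the wild-type arrays and 0.998 between the SGA arrays, and lay between 0.892 and 0.897 for arrays of different groups.

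The distribution of signal itself differed between the groups. Before any scaling the median plant probe had a signal of 233 ± 7.4 in wild type and 523 ± 29 in SGA (SD, n = 2 each), while the upper end hardly moved: the 99th percentile differed by 0.068 on the log2 scale and the 99.9th by -0.089. The 7 spike-in probes, synthetic RNAs added as an external standard, differed by 0.018 on average, with differences per probe from -0.052 to 0.086. That average covers opposite values within the slides, -0.13 on slide 1 and 0.17 on slide 2, where the median tested probe differed by 0.96 and 1.15 before scaling. The brightest 1% of probes held 37.1% ± 0.13 of all signal in wild type and 30.6% ± 0.37 in SGA (SD, n = 2 each). The 378 probes that were brightest in wild type together held 37.1% of the signal in wild type and 24.5% in SGA, and the 378 that were brightest in SGA held 27.9% and 30.6%. A set chosen on 1 group is expected to hold less in the other; 229 probes were in both sets. With 2 arrays per group, no exact test of these single values can give a p below 0.333.

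**Figure D1:**
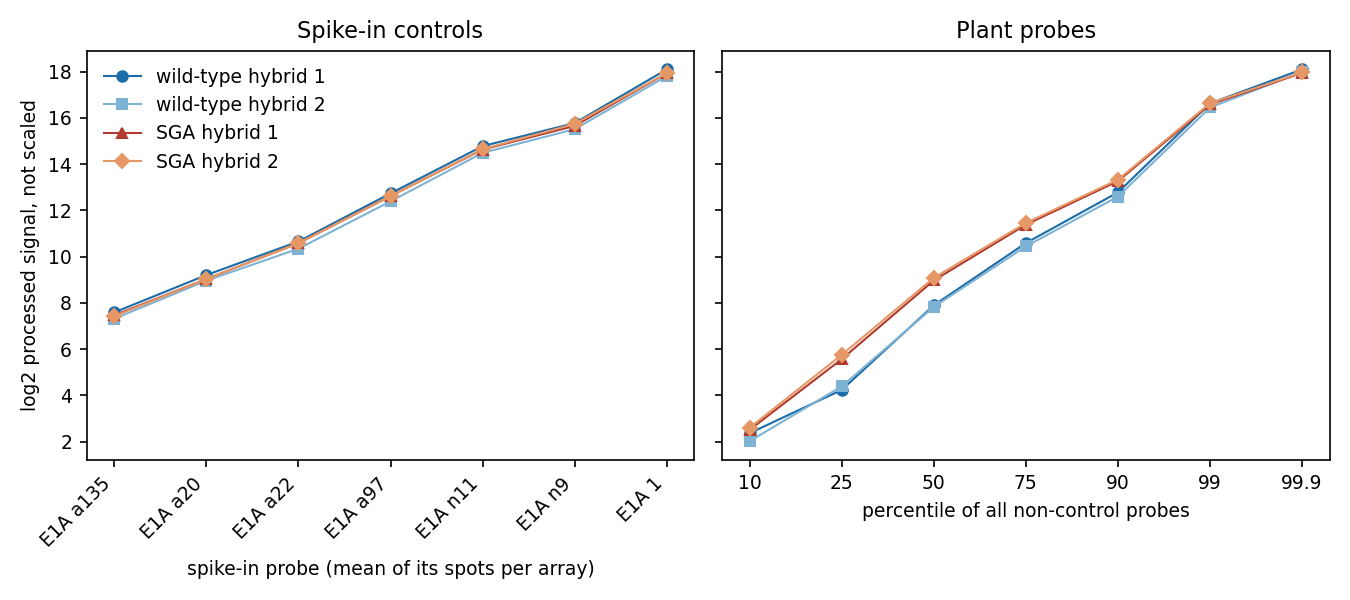
Log2 processed signal without scaling on the 4 arrays, for the 7 spike-in probes (left, mean of 32 spots each) and at 7 percentiles of the plant probes (right); each line is 1 array. The spike-in means were 12.69 and 12.41 on the wild-type arrays and 12.56 and 12.57 on the SGA arrays. The SGA arrays lie between the wild-type arrays, so the mean difference between the groups was 0.018. For plant probes the SGA arrays lie above the wild-type arrays at the 25th, 50th and 75th percentiles and meet them at the 99th.

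Relative to the 75th percentile of each array, 12943 of 30005 tested probes rose in SGA and 8944 fell (limma, adjusted p under 0.05), and 8118 did not pass. Many of the calls were small: 5557 of the rises and 3006 of the falls were under 1.5-fold, and the median absolute log2 difference of called probes was 0.72, with a median standard error of 0.066. At least 2-fold differences were called for 3902 probes that rose and 3650 that fell, and at least 4-fold differences for 1643 and 1731. The groups did not overlap for 88.5% of tested probes, where chance gives 33.3%. The balance of rises and falls depended in part on the filter, which admits a probe through 1 group alone. Without the filter on dim probes 12415 probes rose and 12182 fell. That count includes probes at background, which the scaling tends to place lower in SGA. Before scaling the 10th percentile was 0.36 log2 units higher in SGA, while the 75th percentile that was subtracted was 0.90 higher. The even split is therefore not a less biased count. Among probes above background on all 4 arrays 11531 rose and 8873 fell. The direction of many differences depended on the scaling. Of 30005 tested probes, 6107 were called higher under 1 of the 6 scalings shown and lower under another. The median tested probe differed by 0.16 on the log2 scale with the 75th percentile, by -0.11 with median scaling, by 0.57 in the authors' deposited values, by 0.79 with total-signal scaling and by 1.04 with spike-in scaling. Rises made up 59.1%, 40.2%, 78.2%, 84.1% and 88.7% of the calls in that order, and 45.6% after normexp background correction. Across the 6 scalings shown, 7870 probes rose and 2959 fell under each, of which 2722 and 1884 passed 2-fold each time. All of these scalings except quantile normalization shift every probe alike.

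**Figure D2:**
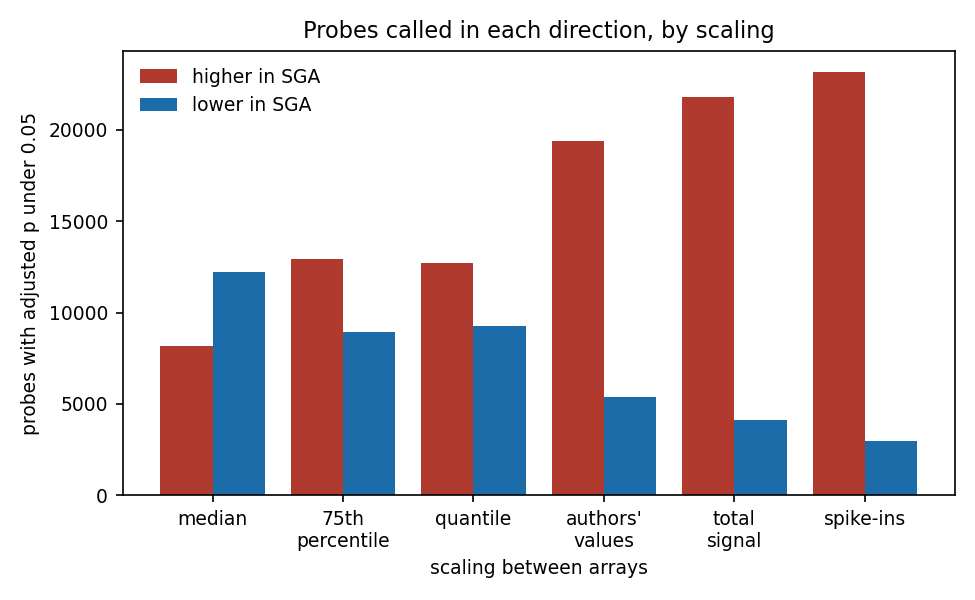
Number of probes (vertical axis, starting at 0) that rose or fell in SGA at an adjusted p under 0.05 (limma) under 6 scalings between arrays. With median scaling 8198 rose and 12194 fell, and with spike-in scaling 23167 rose and 2959 fell.

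Each of the 2 slides carried 1 array of each group. On slide 1, 4299 tested probes were at least 2-fold higher in SGA and 3685 at least 2-fold lower, and on slide 2 the counts were 3947 and 3780. Of these, 3530 were higher and 3443 lower on both slides. With the slide as a block 13559 probes rose and 9363 fell. Leaving out either of the SGA arrays lowered the numbers of rises and falls. The spread then came from the wild-type arrays alone, whose median absolute replicate difference was 0.090 log2 units, against 0.061 for the SGA arrays.

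The probes with the largest differences among those measured on all 4 arrays are given by name; the files do not pair these names with genes. Probe wheat0130Contig5354 rose 345-fold, from signals of 102 and 91.3 in wild type to 60443 and 64086 in SGA (log2 difference 8.43 ± 0.047 SE, n = 2 per group; limma, adjusted p = 4.68e-05). Probe wheat0130Contig12132 rose 277-fold, from 41.0 and 35.6 to 19470 and 20161 (8.12 ± 0.052 SE; limma, adjusted p = 4.68e-05). In the other direction, probe MUGEST2003_23lib_Contig25028_1666 was 1044-fold lower, with signals of 24109 and 20906 in wild type and 39.3 and 41.1 in SGA (-10.03 ± 0.052 SE; limma, adjusted p = 4.68e-05). Probe whsh_allContig1026 was 496-fold lower, with 14892 and 14086 in wild type against 51.6 and 57.7 in SGA (-8.95 ± 0.061 SE; limma, adjusted p = 4.68e-05). The folds are after scaling, and the signals before it. Within slides 1 and 2 the log2 differences were 8.42 and 8.44, 8.10 and 8.13, -10.05 and -10.00, and -8.97 and -8.94, in the order given, and with the slide as a block each probe had an adjusted p = 0.000487 (limma). The size of these folds depended on the processing. With normexp on median spot intensities and an offset of 50, the log2 differences were 7.79, 6.85, -8.64 and -7.65 in the same order, and with quantile normalization added 8.16, 7.21, -8.10 and -7.22. They were 9.31, 9.001, -9.14 and -8.07 with spike-in scaling, and 9.07, 8.75, -9.39 and -8.32 with total-signal scaling. Direction and call were the same over the 19 alternatives run. The probes were picked for their fold, which is far larger than the shifts between scalings, and several alternatives leave the fold as it is. The shared direction is therefore no test of stability.

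More probes were above background in SGA only than in wild type only. Detection was judged on unscaled signal, for which the median plant probe was 2.25 times brighter in SGA. On both SGA arrays and neither wild-type array, 1644 probes were well above background, of which 918 had a lower bound under 2-fold after scaling and 726 were at least 2-fold, 232 at least 10-fold and 31 at least 100-fold higher as a lower bound, with the highest bound at 1480-fold. The reverse held for 256 probes, of which 253 were at least 2-fold, 62 at least 10-fold and 5 at least 100-fold lower in SGA, with the highest bound at 1390-fold. In the fit 1403 of the 1644 probes and all 256 had an adjusted p under 0.05 (limma), which their choice on the same arrays largely sets. Leaving out an array drops a condition from the rule, so either count could only stay or grow, which is no test of stability. Without wild-type replicate 2 the first was 2523, and without wild-type replicate 1 the second was 566. A less strict detection flag gave 993 and 263.

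Relative to the 75th percentile, the brightest probes lay lower in SGA than probes of middle and low signal. Among probes measured on all 4 arrays, the brightest 10% by mean signal had a median log2 difference of -0.40, with 1769 of 2707 probes lower and 370 higher, whereas the dimmest 10% had a median of 0.092, with 655 lower and 874 higher. Spike-in and total-signal scaling shift every probe alike, so they raise the counts of higher probes (1662 and 1446 of the 2707) and leave the gap between bright and dim probes as it is. Quantile normalization, which gives every array the same distribution, did change the pattern: the brightest 10% then had a median of 0.27, with 688 lower and 1484 higher, against 0.13 for all tested probes. Of the 378 probes brightest in wild type, 355 were lower and 3 higher relative to the 75th percentile, and of the 378 brightest in SGA 279 were lower and 35 higher. For the former set the counts were 156 and 125 with quantile normalization.

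The probe names form classes by their leading letters, and 1 class stood apart. Of 906 tested probes whose names begin with whsh_allContig, 589 fell in SGA and 187 rose, 443 fell by at least 2-fold and 50 rose by as much. The class median lay -1.11 log2 units from that of all tested probes, and within slides 1 and 2 it lay -1.12 and -1.06 from it. The class made up 14.9% of the plant signal in wild type and 6.29% in SGA. It supplied 85 of the 378 brightest wild-type probes, and 23 of the 378 brightest SGA probes, where 11.4 were expected by chance in each, and 332 of the 1731 probes that fell at least 4-fold, where 52.3 were expected. Limma's camera gave an adjusted p = 1.27e-14 over 35 classes with the preset correlation and an adjusted p = 0.396 with an estimated correlation. Under the estimated correlation 0 of the 35 classes passed. With spike-in scaling, 416 of the 906 probes fell and 398 rose, and the class median was -0.066. Probes named rwhr lay 0.28 log2 units above all tested probes (0.26 and 0.29 within slides 1 and 2), with 151 of 254 higher, 43 lower and 83 at least 2-fold higher (adjusted p = 0.00277, and adjusted p = 0.396 with an estimated correlation). The class MUG lay -0.35 from all tested probes, with 581 of 1227 lower and 297 higher (adjusted p = 0.000677, and adjusted p = 0.423 with an estimated correlation). With quantile normalization it lay 0.0034 from all tested probes, with 295 lower and 518 higher, so its direction rests on the scaling. The class rwhoh had 169 of 288 probes higher and 50 lower (adjusted p = 0.0485, and adjusted p = 0.995 with an estimated correlation). With quantile normalization rwhr lay 0.25 and rwhoh 0.12 above all tested probes; the other scalings shown shift every probe alike and leave these distances as they are. The classes were formed after the data were seen, and what their letters stand for is not given in the sources used here.

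**Figure D3:**
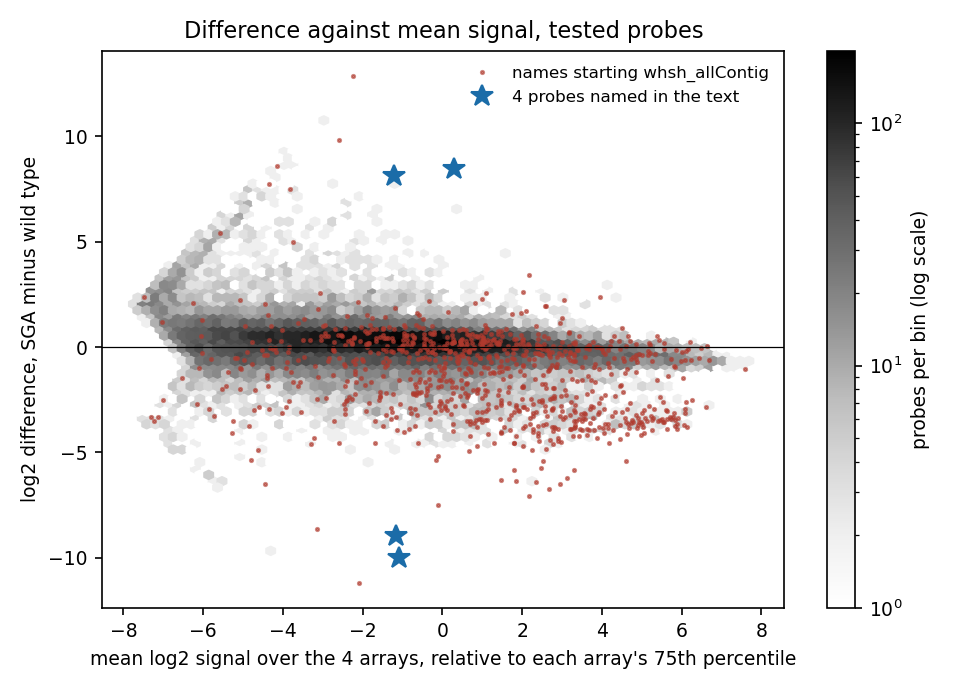
Log2 difference (SGA minus wild type) against mean log2 signal relative to the 75th percentile for the 30005 tested probes, as counts per bin on a log colour scale. Red points are the 906 probes named whsh_allContig, of which 443 fell at least 2-fold, and stars mark the 4 probes given by name.

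Only 6 probes bear a gene symbol. DREB2A, DREB2B, RD29A, cor47 and Wcor15, named after genes of the cold and dehydration response, were not well above background on any array. RD29B, another gene of that response, was above background on 3 arrays and did not pass the test. Its signals before scaling were 24.9 and 34.9 in wild type and 44.8 and 58.4 in SGA. The 75th percentiles used for scaling were 1541 and 1395 in wild type and 2671 and 2813 in SGA. The probes with a gene symbol cover 4 names of the list for cold and dehydration, too few for a test of the list. Of 41 probes named by a sequence accession, 18 were tested, 13 rose and 3 fell.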

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

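The spike-in and total-signal scalings, and every alternative for the probes above background in 1 group, for the share of signal and for the name classes, were chosen after seeing the data. Rises numbered 8198 with median scaling, 23167 with spike-in scaling and 21779 with total-signal scaling; falls numbered 5389 in the authors' values, 2959 with spike-in scaling and 4119 with total-signal scaling. Each scaling sets the level of the median probe, which moved from -0.11 to 1.04. Requiring at least 2-fold left 3902 rises and 3650 falls; without a test, no overlap and at least 2-fold gave 4016 and 3669, and at least 4-fold gave 1656 and 1734. Leaving out each array gave 8498 to 13585 rises and, as a range for the on-off counts, 1721 to 2523 probes above background in SGA only and 284 to 566 in wild type only; the other detection flag gave 993 for SGA only. The replicate block, the same fit as the slide block, gave 13559 rises and 9363 falls and changed the call of none of the 4 named probes and 3 name classes compared. The change in the share of signal held by the brightest probes was -6.52 percentage points for the brightest 1%, -1.74 for the brightest 0.1% and -7.00 for the brightest 10%. For the name class whr, the shift from all probes (0.19) turned to -0.019 with quantile normalization and -0.054 with normexp, and the cause was not tested; its test gave an adjusted p = 0.161 and passed in 1 of 14 alternatives, without wild-type replicate 2 (range of adjusted p over the alternatives 0.0435 to 0.995). The classes whsh_allContig and rwhr kept their direction under each of their 14 alternatives. Of these, median, authors', spike-in and total-signal scaling, the block and the estimated correlation could not change it. They leave the distance from all probes as it is. Both classes lost their call only with an estimated correlation (limma's camera, adjusted p from 5.52e-30 to 0.396 and from 0.000494 to 0.396). Leaving out saturated probes or keeping 1 probe per name changed nothing, since no spot was saturated and no name repeated. Signal over background limits the rest: 6578 probes were above background on no array and have no direction here. Alternatives for gene list shifts were not run, because the lists matched only 4 probe names, too few for a test.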

Other observations

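The removal of the brightest probes and the signal-matched random lists were set before their outcome was seen. The spike-in shift, both tests of a uniform rise, the p and m pairs and all other values here were chosen after the data were seen.

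Among the 2707 brightest probes measured on all 4 arrays, 269 had names beginning with whsh_allContig. Their median log2 difference was -2.37, with quartiles of -3.50 and -0.40, and that of the other 2438 probes was -0.36. Of the 269 probes, 144 (53.5%) fell at least 4-fold in SGA, against 188 of the others (7.71%).

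A general tendency of bright probes to lie lower does not explain the whole class: its median of -0.95 lay below the lowest of 10000 random lists matched on mean signal, which was -0.16. What the class letters stand for is not given, and no biological explanation was tested, so the phenotype itself stays open. Several contigs of the class may also come from the same gene or cross-hybridise, so that fewer transcripts changed than probes, which was not tested. The loss of the call in limma's camera with an estimated correlation (adjusted p = 0.396) cannot decide this. With that setting 0 of 35 classes passed. An effect of the position on the slide on these probes alone cannot be told apart from the phenotype. The classes whr and rwhr taken as 1 list had a median of 0.39, and the highest of 10000 matched lists 0.38, but whr alone (0.35) lay within its matched range of 0.20 to 0.39, 13 of 35 classes lay outside theirs, and neither class passed with an estimated correlation (limma's camera, adjusted p = 0.995 and 0.396).

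The typical probe was brighter in SGA than in wild type against the spike-in controls, by 1.04 log2 units. The spike-in probes argue against a difference in array response. Their mean shift was 0.018 (SD 0.049 over 7 probes, -0.13 and 0.17 within slides 1 and 2) where the median plant probe shifted by 1.06 (0.96 and 1.15). For a few bright wild-type probes as the cause, the difference of 0.79 with total-signal scaling was still 0.56 without the 543 probes in the top 1% of any array. Spike-in scaling uses no plant probes, so this test cannot decide the cause of the difference against the spike-in controls. A uniform rise of all transcripts was first tested by the gap in median log2 difference between the dimmest and brightest 10% of probes, which was 0.497, just under the 0.5 set as evidence against it, and so decided nothing. The share of signal in the brightest 1% of probes was tested only after that result, and was itself already known. It changed by -6.52 percentage points, where a uniform rise leaves shares unchanged. This argues against a uniform rise as the whole cause, but is weaker evidence for having replaced an undecided test. The percentiles before scaling argue against it too, since a uniform rise moves each alike. SGA lay higher by 1.17, 0.90, 0.61 and 0.068 log2 units at the 50th, 75th, 90th and 99th percentiles. Bright wild-type probes as a cause stay open. So do a combination of these explanations and a less concentrated transcript population in SGA crowns, which may be biological. Neither of the latter was tested. The amount and quality of the plant RNA, which spike-in probes do not measure, were not tested either.

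The array holds 833 pairs of probes that share a contig or clone name and differ in the letter p or m. Both probes were measured in 108 pairs, only p in 323, only m in 164 and neither in 238, while 10000 random re-pairings gave a median of 141 pairs with both measured and a lowest count of 113. This is consistent with the letters marking opposite strands of which usually 1 carries the transcript, a reading of the names that no source used here states. In the 73 pairs measured on all 4 arrays the log2 differences of p and m correlated across pairs, which are not independent replicates (Spearman's rho = 0.32, permutation p = 0.0062, Benjamini-Hochberg adjusted 0.0124; Pearson's r = 0.27, permutation p = 0.0244, adjusted 0.0244; 2 relations computed). Of 37 pairs with both probes called, 26 moved the same way and 11 in opposite ways.

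The control probe (+)eQC-40 had signals of 1422 and 2004 in wild type and 114 and 173 in SGA, a 12.2-fold lower level after spike-in scaling, while each of the 14 control probes named DCP that were well above background differed by at most 1.11-fold. The median absolute difference between replicates, over probes measured on all 4 arrays, was 0.090 log2 units in wild type and 0.061 in SGA. Across the 32 spots of a spike-in probe the SD, as a median over the arrays, was 0.037 to 0.10.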
